A study of Ovis aries with 9 samples.

How the data were processed

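Droplet single-cell RNA sequencing (10x Genomics 3' chemistry, version 3.1, per the labels) was measured on the tail of embryos of the Tan sheep, a fat-tailed breed, at 9 stages from embryonic day 50 (E50) to 80 (E80), with the stages E55, E60, E63 and E66 in the earlier part and E69, E72 and E75 in the later. Each stage had 1 library. Per the labels, the tissue was dissociated with collagenase IV, DNase I and trypsin, strained, and treated to lyse red cells. Per the file headers, the values are raw UMI counts per gene and cell barcode from Cell Ranger 6.0.0; the submitters' processing notes name Cell Ranger 6.0 and also Seurat, without saying for which step. The genome build and the annotation were not given in the sources used here, so no gene positions are printed. A UMI is a molecular tag that counts each captured RNA molecule once.

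The 9 libraries held 49415 barcodes, and the smallest barcode held 500 UMIs. Barcodes with fewer than 500 genes (2832) or with more than 20% of UMIs from mitochondrially encoded genes (1072, some meeting both) were left out, which kept 46277. Doublets, droplets with more than 1 cell, were predicted within each library from 2 simulated doublets per cell, and the highest-scoring cells were removed at 0.8% per 1000 cells. This removed 2167 cells (4.68%) and left 44110. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used for the cells, and R 4.3.3 for the tests.

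Cells were scaled to 10000 UMIs, log transformed, and reduced to 30 principal components of 2000 variable genes. A graph of 15 neighbours was clustered by the Leiden method at resolution 1.0. All libraries were clustered together, with no correction for differences between libraries. The 45 clusters, 3 of them with under 10 cells, were named from 19 lists of cell type markers. A marker counted for a cluster when at least 10% of its cells held it and its level was at least 3 times the median of the clusters it was compared with. A cluster took the class with the largest share of its list met, from at least 3 markers. The lists were fixed before the data were examined. The rules for awkward clusters were set after the clusters were seen, in several rounds: a cluster with under 33.3% of its library's median UMIs, one with haemoglobin among its top 3 genes (at first its top 10), one led by immunoglobulin genes, or one whose top 10 genes held more markers of another class stayed unnamed, and a second-choice name needed markers of its own among those genes. The 37 named clusters formed 9 classes, written with "-like" since no label names cell types. There was no erythroid-like class, so shares of non-erythroid-like cells were not computed separately.

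UMI counts were summed per library over all kept cells (whole-tissue sums) and over each class with at least 30 cells in at least 7 libraries. With 1 library per stage no pair of stages was tested. The slope of log2 expression on embryonic day, in log2 units per 10 days, was tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, low counts filtered, Benjamini-Hochberg adjustment, threshold 0.05), and SE is the slope divided by the root of its F. Expression levels (CPM) are UMIs per 1000000 UMIs of the sum. The 40 gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with an estimated correlation and fry beside it. A list needed at least 3 tested genes. Class shares were correlated with day by Pearson's r and Spearman's rho with two-sided exact permutation tests over all orders of the libraries. Intervals are at 95%, exact Clopper-Pearson for shares and exact Poisson or binomial for counts and their ratios. They and the limit of 3 counts for a count of 0 cover counting error only.

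The genes named for the whole-tissue and the mesenchymal-like trend were, among those past the threshold with a symbol, a mean of at least 20 CPM and the same sign of slope with each library left out, the 12 with the largest rise and the 12 with the largest fall. For every other class the rule took 3 in each direction. Symbols made of LOC and a number were treated as identifiers, which was decided after seeing the data. Which members of a gene list are named was chosen after their values were seen. Tested on simulated data, the fit recovered 93% of slopes of 0.5 and 100% of slopes of 1 in the whole-tissue sums, with 4.46% false calls. The simulated genes had straight slopes, a common dispersion and no step between E66 and E69, and only genes of at least 20 CPM were given a slope. The rates therefore do not carry over to data with such a step.

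Alternatives were DESeq2 1.42.0, scaling by library size alone, no filter, the rank of the stage in place of the day, equal cells and UMIs per library (2070 cells and 15329989 UMIs), stricter cells (1000 genes, 10% mitochondrial UMIs), doublets kept, no haemoglobin genes, Leiden resolutions of 0.5 and 2.0, classes from marker scores, and each library left out. The 5 libraries up to E66 and the 4 from E69 differed most between neighbouring stages, so after seeing the data a term for that split, fits within each side, a fit up to E69, and class shares centred on each side were added. Also added after seeing the data were unnamed clusters with haemoglobin in the top 10 and low-depth clusters named by their markers.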

Results

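Tail tissue of Tan sheep embryos was profiled in 9 single-cell libraries, 1 per stage from E50 to E80, with no replicate at any stage. The libraries held between 28020534 (E50) and 63389520 UMIs (E80), and between 2070 (E50) and 7412 (E80) cells were kept. The totals between were 47099196 UMIs at E55, 34344081 at E60, 40086428 at E63, 49168556 at E66, 55625842 at E69, 55760664 at E72 and 51419468 at E75. The median depth of a kept cell was 11348 UMIs at E50, 8547 at E66, 6866 at E69 and 6121.5 at E80, so it was lower at later stages. The median share of mitochondrially encoded UMIs was 0.637% at E50, 1.98% at E66, 2.64% at E69 and 2.63% at E80. The data had 20477 genes, 1908 of them with an identifier and no symbol.

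By clustering, fat cells were found from E69 on: the cluster with an adipocyte-like profile held no kept cell of E50 to E66 and 2.52% of the kept cells at E80. Muscle cells were most frequent around E72, and connective tissue cells were the most frequent class at every stage. Adipocyte-like cells, led by FABP4 and FABP5 (fatty acid carriers), LPL (lipoprotein lipase), SCD (a fatty acid desaturase), ADIPOQ (the hormone adiponectin) and CIDEA (a lipid droplet protein), numbered 19 at E69 (0.295%, interval 0.177 to 0.460), 54 at E72 (0.822%, 0.618 to 1.07), 159 at E75 (2.55%, 2.18 to 2.98) and 187 at E80 (2.52%, 2.18 to 2.91). None of the cluster's cells were in the 5 earlier libraries, which allows shares in it of up to 0.145% at E50, 0.0728% at E55, 0.105% at E60, 0.0853% at E63 and 0.0613% at E66. Marker scores also put cells of the earlier libraries in the adipocyte-like class, with shares of 1.54 (E60) to 3.92% (E66) up to E66 and 5.15 (E69) to 13.8% (E80) from E69. All cells up to E66 together held 3 ADIPOQ, 5 PLIN1 and 1 CIDEC UMIs, beside 465 of FABP4 and 781 of LPL. Few of the early cells scored so can thus have held ADIPOQ, PLIN1 or CIDEC. Of all kept cells 20.4% had their highest and next score within 0.1. The 419 cells of the cluster had a median of 20850 UMIs, 3.35 times that of their libraries. Skeletal-muscle-like cells were 12.4% at E66, 23.5% at E69, 33.6% at E72 (interval 32.5 to 34.8), 24.5% at E75 and 13.8% at E80. Mesenchymal-like cells, the connective tissue class, were 67.0% at E50, 54.3% at E72 and 63.8% at E80.

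Over the 9 classes, no share passed by Pearson's r after adjustment, and 4 passed by Spearman's rho (two-sided exact permutation tests, 9 libraries, adjusted over the 9 classes). The adipocyte-like share had r = 0.801 (p = 0.00661, adjusted p = 0.0595) and rho = 0.895 (adjusted p = 0.0238), with r = 0.755 without E50 and E80. The muscle-like share had r = 0.546 (p = 0.128, adjusted p = 0.193) and rho = 0.767 (adjusted p = 0.0481), with r = 0.825 without E50 and E80. For the mesenchymal-like share r was -0.664 (p = 0.048, adjusted p = 0.119) and rho -0.817 (adjusted p = 0.0481), with r = -0.886 without E50 and E80. The tenocyte-like share, of tendon cells, gave r = -0.696 (p = 0.0362, adjusted p = 0.119), rho = -0.767 (adjusted p = 0.0481) and r = -0.858 without E50 and E80. Schwann-like (r = -0.638, rho = -0.717), keratinocyte-like (-0.622, -0.567), endothelial-like (0.388, 0.267), mural-like (0.109, 0.117) and macrophage-like shares (0.0719, 0.0167) passed by neither. For the keratinocyte-like share r was -0.179 without E50. The muscle-like share ran from 10.1 to 12.4% in the 5 libraries up to E66 and from 13.8 to 33.6% in the 4 from E69, and the mesenchymal-like share from 66.3 to 73.6% and from 54.3 to 64.5%. With shares and days centred on each side of that split and permuted within the sides (exact permutation test, chosen after seeing the data), 0 of the 9 classes passed by r or by rho. There r was 0.478 for adipocyte-like (adjusted p = 0.437), -0.348 for muscle-like (0.536), -0.0999 for mesenchymal-like (0.886), and -0.192 for tenocyte-like shares (0.886). It was 0.797 for endothelial-like (0.0547), 0.801 for mural-like (0.0547), -0.584 for keratinocyte-like (0.437), 0.309 for macrophage-like (0.649) and 0.00481 for Schwann-like shares (0.990). The adipocyte-like share was 0 in every library up to E66, so only orders of the 4 libraries from E69 could change its r. Those orders are too few for it to pass after adjustment in practice, so this test decides nothing about the adipocyte-like share. The count of 4 was 1 without E55, E60 or E66, 2 without E63, and 0 without E69, E72 or E75, and the count by Pearson's r was 2 without E50 and 1 without E75. With classes from marker scores, which gave 66.3% of the cells the same class, rho for the mesenchymal-like share was -0.383 (adjusted p = 0.461) and for the muscle-like share 0.350 (adjusted p = 0.461).

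**Figure D1:**
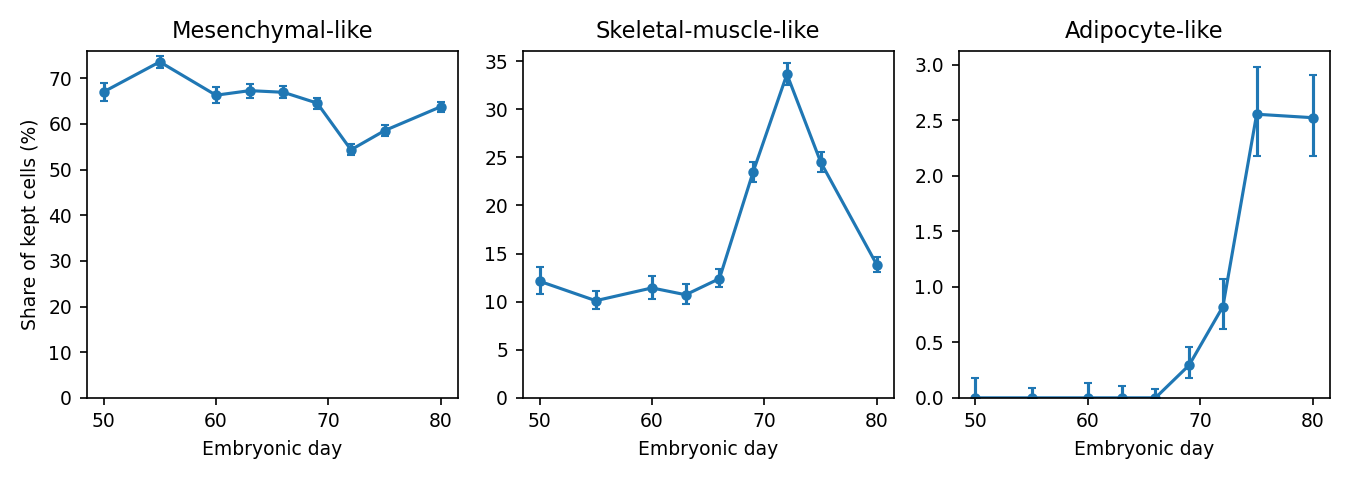
Share of the kept cells (%) against embryonic day for mesenchymal-like, skeletal-muscle-like and adipocyte-like cells. Points are libraries, 1 per stage, and bars are 95% Clopper-Pearson intervals of counting error; the muscle-like share peaks at 33.6% at E72 and the adipocyte-like share, by clustering, leaves 0 at E69.

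Across the whole tail, most tested genes of fat storage rose with embryonic day, led by a carrier of fatty acids, while a binder of retinoic acid fell. FABP4 rose by 4.19 log2 units per 10 days (SE 0.49, n = 9 libraries, adjusted p = 0.00162), from 0.634 CPM at E50 to 619 CPM at E80. Slopes of whole-tissue sums mix changes of class shares with changes of expression within cells. Over all libraries from E69 the whole tissue held 66671 FABP4 UMIs. Adipocyte-like cells held 30085 of them at E80, and mesenchymal-like cells 2847. PPARG, the master transcription factor of fat cell formation, rose by 1.02 (SE 0.10), from 9.96 to 99.4 CPM. CRABP1, which binds retinoic acid in the cytoplasm, went the other way at -1.09 (SE 0.15, adjusted p = 0.0024), from 2038 to 277 CPM. Of 12769 genes tested, 3197 changed with day, 1472 rising and 1725 falling (828 and 2346 with scaling by library size alone).

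Of the adipocyte and lipid genes, 22 of 27 rose and 0 fell (26 and 0 adjusted over the list alone), with a median slope of 0.87. The list passed camera (adjusted p = 2.18e-11), but not with an estimated correlation (adjusted p = 0.472 with an estimated correlation). LPL rose by 1.95 (SE 0.26), CIDEA by 1.97 (SE 0.25), SCD by 1.84 (SE 0.27) and FASN, the fatty acid synthase, by 0.93 (SE 0.16). DGAT2, which makes triglycerides, rose by 1.38 (adjusted p = 0.019, and 0.0686 without E80). PLIN2, a lipid droplet coat protein, had a slope of 0.11 (adjusted p = 0.0992). Pooled over libraries, ADIPOQ had 3 UMIs up to E66 and 1556 from E69, a ratio of levels of 476 (interval 163 to 2311), and PLIN1, the coat protein of large lipid droplets, had 5 and 154 (ratio 28.3, 11.9 to 88.3). UCP1, the heat-producing protein of brown fat, had 8 and 11 UMIs (ratio 1.26, 0.462 to 3.61), a difference not detectable at this depth. Of the brown fat genes 1 of 10 rose, CIDEA, which white fat also holds, 0 fell (1 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.876). Of the adipogenic transcription factors 5 of 22 rose and 4 fell (5 and 4 adjusted over the list alone), and that list did not pass (adjusted p = 0.678). Among them were PPARG, CEBPA (slope 0.76, adjusted p = 0.00775, and 0.0722 without E80), a partner of PPARG in fat cells, and CEBPD, an early factor of fat cell formation, at -1.21 (SE 0.30, adjusted p = 0.0227, and 0.0755 without E80). CEBPD was 49.8 CPM at E66 and 15.1 CPM at E69, and its slopes were -0.37 within the libraries up to E66 and 0.22 within those from E69. Of the adipose progenitor genes 5 of 24 rose and 2 fell (6 and 4 adjusted over the list alone, list adjusted p = 0.538). DLK1, an imprinted inhibitor of fat cell formation, rose by 0.55 (SE 0.09), from 2459 to 6026 CPM.

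The other named risers were CLEC3B (tetranectin, 0.76, SE 0.04, adjusted p = 1.79e-05), NUPR1, a stress-responsive nuclear protein (1.18, SE 0.08), FABP5 (1.09, SE 0.17), CRYAB, a small heat shock protein (1.08, SE 0.23), FGL1 (0.86, SE 0.16), PLAAT3 with the identifier ENSOARG00020022912 (0.82, SE 0.09) and MYLK, the kinase of myosin light chains (0.80, SE 0.08). The heat shock genes HSPA1A (2.28, SE 0.60, adjusted p = 0.0269) and DNAJB1 (1.39, SE 0.32, adjusted p = 0.0163) also rose. HSPA1A was 6.73 CPM at E69, 344 at E72, 79.4 at E75 and 274 at E80. The HSPA1A call ended without E50 (adjusted p = 0.0828), E55 (0.0664) or E80 (0.0714), and the DNAJB1 call without E50 (0.0559) or E80 (0.055). Named fallers included SNCG, a synuclein of sensory neurons (-1.68), PTGES, which makes prostaglandin E2 (-1.16), COL2A1, the main cartilage collagen (-1.16), UCHL1, a neuronal ubiquitin hydrolase (-1.04), TNC, a matrix protein of developing connective tissue (-1.02), MFAP2 of elastic microfibrils (-1.01), HOPX (-0.92) and SMOC2 (-0.89). CCER2 had the steepest fall (-2.04, adjusted p = 0.0256), which ended without E50 (0.563), E72 (0.0519), E75 (0.0572) or E80 (0.067). The fall of SNCG ended without E72 (0.0571), E75 (0.0536) or E80 (0.0818), and that of CDH6, a cadherin (-0.96), without E55 (0.0593), E75 (0.0536) or E80 (0.0879).

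**Figure D2:**
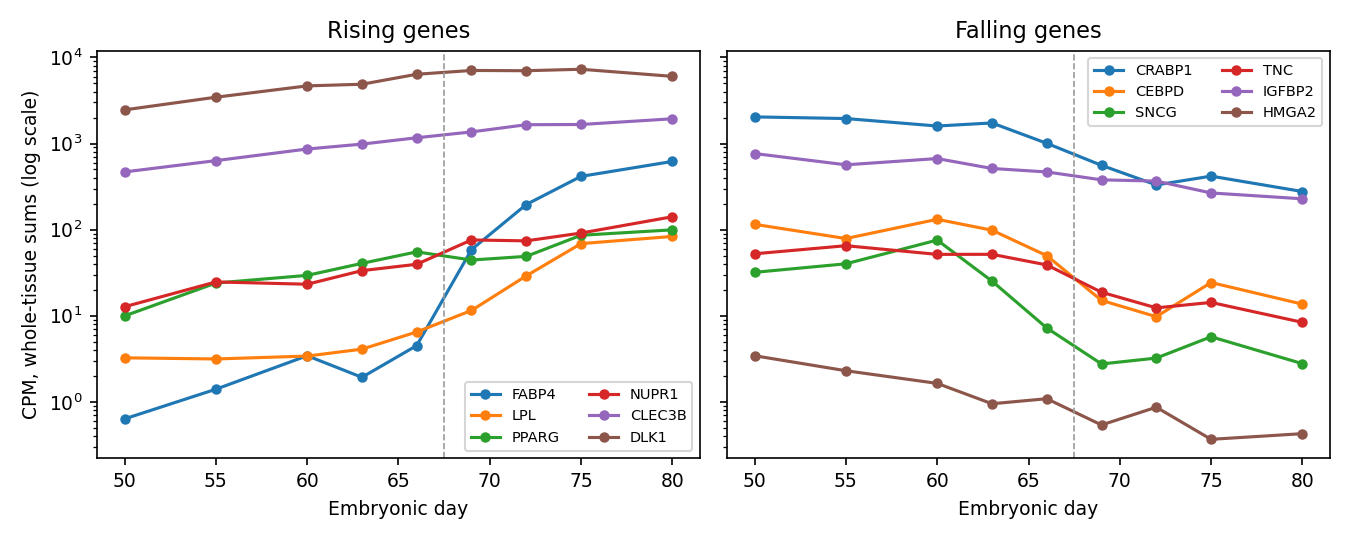
Whole-tissue expression (CPM, log scale) against embryonic day for 12 genes, 1 point per library; the left panel holds FABP4, LPL, PPARG, NUPR1, CLEC3B and DLK1 and the right panel CRABP1, CEBPD, SNCG, TNC, IGFBP2 and HMGA2. The dashed line stands between E66 and E69, where CEBPD went from 49.8 to 15.1 CPM.

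Among signalling genes, the Wnt pathway and IGF axis lists had more fallers than risers and the Notch list more risers. Of the Wnt pathway genes, 12 of 22 fell and 0 rose (12 and 1 adjusted over the list alone; list adjusted p = 0.000228, 0.472 with an estimated correlation). They included RSPO2, which strengthens Wnt signals (-0.78, SE 0.13), WNT5B (-0.76, SE 0.09) and the secreted Wnt modulator SFRP2 (-0.49, SE 0.08). Of the IGF axis genes, which regulate growth, 9 of 18 fell and 2 rose (10 and 3 adjusted over the list alone; list adjusted p = 0.00345, 0.472 with an estimated correlation). HMGA2, a chromatin protein of embryonic growth, fell by 1.01, IGF2BP1, an RNA-binding protein of the embryo, fell by 0.62, and IGFBP2 fell by 0.53, while the growth factor IGF1 rose by 0.50. Of the Notch pathway genes, 6 of 14 rose and 0 fell (10 and 0 adjusted over the list alone; list adjusted p = 0.000725, 0.472 with an estimated correlation), among them the target HES1 (0.58, SE 0.10). Of the posterior HOX genes, which pattern the tail end of the body, 2 of 11 rose and 5 fell (2 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.0728). With a term for the split of the libraries between E66 and E69, the Wnt (adjusted p = 0.173) and IGF lists (0.221) no longer passed, the Notch list did (0.00575), and the posterior HOX list passed downward (0.00974).

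Vessel and macrophage genes had more risers than fallers in the whole-tissue sums, and genes of the neuronal list had fallers alone. Of the endothelial genes, 8 of 13 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.00273, 0.569 with an estimated correlation), with the junction proteins CDH5 at 0.69 and PECAM1 at 0.48. The 1 that fell was EGFL7, a secreted vessel protein (-0.42), and its call ended without E50 (adjusted p = 0.151) or E75 (0.0598). Of the macrophage genes, 6 of 10 rose and 0 fell (7 and 0 adjusted over the list alone; list adjusted p = 0.00153, 0.472 with an estimated correlation). The complement gene C1QA (0.42, adjusted p = 0.00933) and the adaptor gene TYROBP (0.42, adjusted p = 0.0077) were among them, and their calls ended without E50 (0.0557 and 0.0512). A cluster that met 8 macrophage markers, C1QA and TYROBP among them, stayed unnamed for its immunoglobulin RNA. It made up 0.145% of the kept cells at E50 and 0.594% at E80, and its part in these rises was not tested. Of the neuronal genes, 5 of 9 fell and 0 rose (6 and 0 adjusted over the list alone; list adjusted p = 0.0269, 0.472 with an estimated correlation, and 0.205 without E50). The neurofilament gene NEFM was at -0.83 and STMN2, of growing axons, at -1.08 (adjusted p = 0.0169, and 0.054 without E80). No class was neuron-like. Of the NEFM UMIs, 5905 of 6073 at E50 and 2444 of 2538 at E80 were in mesenchymal-like cells, and STMN2 was among the top 10 genes of an unnamed cluster with mesenchymal markers. Muscle contractile genes had 0 of 22 risers and 2 fallers (0 and 1 adjusted over the list alone), with a median slope of 0.04 against a camera direction of down, and did not pass (adjusted p = 0.48). MYH3, the embryonic myosin, had a slope of 0.14 (adjusted p = 0.76). With the term for the split at E66 the contractile list passed downward (adjusted p = 1.45e-06), and the slope of MYH3 was -0.79 (adjusted p = 0.377). Of the cartilage matrix genes 2 of 16 rose and 2 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.093).

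All 9 tested mitochondrially encoded genes rose (9 adjusted over the list alone; list adjusted p = 4.85e-06, 0.472 with an estimated correlation), as MT-ND3 did by 0.96, beside the higher mitochondrial share of the later libraries. Cytosolic ribosomal protein genes had 13 of 44 risers and 2 fallers (14 and 2 adjusted over the list alone; list adjusted p = 0.0148, 0.653 with an estimated correlation). Of the dissociation stress genes, known to respond to enzymatic tissue digestion, 9 of 23 rose and 0 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.0355, 0.569 with an estimated correlation), and the list did not pass without E50 (0.283) or E80 (0.131). It passed with the term for the split at E66 (adjusted p = 8.62e-08). Of the G2/M phase genes 8 of 29 fell and 0 rose (8 and 0 adjusted over the list alone; list adjusted p = 0.0148, 0.653 with an estimated correlation, and 0.132 without E55). Of the S phase genes 7 of 31 fell and 0 rose (7 and 0 adjusted over the list alone; list adjusted p = 0.0338, 0.569 with an estimated correlation). The S phase list did not pass without E50 (0.0567), E55 (0.0897) or E75 (0.0592). RRM2, a subunit of the enzyme that makes DNA building blocks, fell by 0.35. Of the glycolysis and hypoxia genes 6 of 24 fell and 0 rose (6 and 0 adjusted over the list alone; list adjusted p = 0.0319, 0.631 with an estimated correlation), and the list did not pass without E55 (0.0747) or E72 (0.0672). Over the 39 lists tested in the whole-tissue sums, 13 passed, 7 up and 6 down, and 0 passed camera with an estimated correlation, while fry called 20 lists, 10 of them among the 13. With the term for the split at E66 the calls of the G2/M phase (adjusted p = 0.321), cytosolic ribosomal protein (0.764, direction down) and glycolysis and hypoxia lists (0.201, direction up) ended.

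The libraries up to E66 and from E69 stood apart, and most whole-tissue calls were lost when that split was a term beside the day: 66 genes passed (30 rising, 36 falling, 53 of them also called before in the same direction). Of the 3197 slopes 95.8% kept their direction with the term. They correlated with the slopes before at r = 0.900. The split itself correlated with day at r = 0.832, so the term also widens the error of a steady slope. The loss of calls therefore does not show that they come from the split. CLEC3B (0.74, adjusted p = 0.00759), PPARG (1.36, adjusted p = 0.00759), NUPR1 (0.93, adjusted p = 0.0249), CDH5 (0.86, adjusted p = 0.0421) and PECAM1 (0.82, adjusted p = 0.0148) passed with the term, and FABP4 did not (2.21, adjusted p = 0.104). Within the 5 libraries up to E66, 30 genes passed, and within the 4 from E69 edgeR called 0, with 1661 at an unadjusted p under 0.05 and no other tool run there. Of the 3197 genes, 91.9% of those tested up to E66 had the same direction there, and 75.1% from E69. The genes were called on slopes over these same libraries, so agreement in direction is in part built in, here and with the term. In the fit up to E69 only, which leaves out E72, E75 and E80, 108 genes passed. The count of 3197 was 2109 without E50, its rising part was 967 without E50 and 876 without E80, and its falling part 1142 without E50.

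In the mesenchymal-like cells, the fat genes FABP4 and PPARG and the genes of the main fibre collagens rose with day, and the retinoic acid binder CRABP1 fell. FABP4 rose by 3.54 log2 units per 10 days (SE 0.26, n = 9 libraries, adjusted p = 0.000107), from 0.0549 CPM at E50 to 85.1 CPM at E80. PPARG rose by 1.04 (SE 0.19) and NUPR1 by 1.40 (SE 0.10, from 14.0 to 219 CPM), while CRABP1 was at -0.98 (SE 0.13, from 2769 to 414 CPM). Of 11639 genes tested, 3040 changed with day, 1418 rising and 1622 falling (612 and 2716 with scaling by library size alone). The class was a mixture whose clusters differed between stages: the cluster with the most cells held 24.7% of the class up to E66, and another held 24.9% from E69. The first of these had 818 cells at E66 and 70 at E69. A further cluster had 196 and 1179, and both held SFRP2, POSTN, COL14A1 and SFRP4 among their top 10 genes. Without correction between libraries, a change of cell types and the same cells set apart by library cannot be told apart.

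Of the adipocyte and lipid genes tested in the mesenchymal-like sums, 12 of 21 rose and 1 fell (12 and 1 adjusted over the list alone; list adjusted p = 9.04e-05, 0.494 with an estimated correlation). LPL rose by 1.18 (SE 0.13), CIDEA by 1.49 (SE 0.21) and SCD by 1.00 (SE 0.15). Of the adipose progenitor genes 11 of 24 rose and 2 fell (11 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.0717). PI16, a marker of early fibroblast-like progenitors, rose by 0.97 (SE 0.21), NT5E, the ectonucleotidase CD73, by 1.13 (SE 0.17) and CD34 by 0.64 (SE 0.09), while LY6E fell by 0.82. Of the adipogenic transcription factors 7 of 19 rose and 3 fell (7 and 4 adjusted over the list alone; list adjusted p = 0.513), and of the brown fat genes 2 of 10 rose and 0 fell (2 and 0 adjusted over the list alone; list adjusted p = 0.446). DLK1 rose by 0.68 (SE 0.08), from 2819 to 8769 CPM. At E80 the FABP4 level was 7380 CPM in adipocyte-like, 308 in mural-like, 85.1 in mesenchymal-like, 19.9 in endothelial-like and 15.8 CPM in muscle-like cells, levels that free RNA in the droplets also feeds.

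Of the fibrillar collagen genes, which form the fibres of skin and tendon, 9 of 19 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.018, 0.56 with an estimated correlation). COL1A1 rose by 0.44 (SE 0.05), COL3A1 by 0.44 (SE 0.05) and COL1A2 by 0.41 (SE 0.05), and the list did not pass without E50 (0.0875) or E55 (0.0669). Of the small leucine-rich proteoglycan genes, which space collagen fibrils, 6 of 10 rose and 2 fell (6 and 2 adjusted over the list alone; list adjusted p = 0.022, 0.50 with an estimated correlation), with lumican (LUM) at 0.38 and decorin (DCN) at 0.33. Of the Wnt pathway genes 10 of 21 fell and 2 rose (10 and 2 adjusted over the list alone; list adjusted p = 0.00464, 0.494 with an estimated correlation), and RSPO2 fell by 0.77. Of the IGF axis genes 8 of 16 fell and 3 rose (9 and 4 adjusted over the list alone; list adjusted p = 0.022, 0.371 with an estimated correlation), with HMGA2 at -1.32 (SE 0.10) and IGF1 at 0.61. Of the G2/M phase genes 8 of 29 fell and 1 rose (8 and 1 adjusted over the list alone; list adjusted p = 0.00464, 0.56 with an estimated correlation). Of the S phase genes 10 of 31 fell and 0 rose (11 and 0 adjusted over the list alone; list adjusted p = 0.022, 0.50 with an estimated correlation, and 0.0669 without E55). Of the lymphatic endothelial genes 3 of 6 fell (4 adjusted over the list alone; list adjusted p = 0.00464, 0.358 with an estimated correlation), with RELN, a secreted guidance protein, at -1.38, podoplanin (PDPN) at -0.71, and the scavenger receptor STAB1 at -0.46 (adjusted p = 0.00714, and 0.0811 without E50). The cluster with lymphatic markers was endothelial-like, so this fall does not describe lymphatic cells. Whether it lies in mesenchymal-like cells or in RNA of other cells was not tested. All 9 mitochondrially encoded genes rose (9 adjusted over the list alone; list adjusted p = 1.49e-05, 0.50 with an estimated correlation), and 22 of 43 cytosolic ribosomal protein genes rose and 2 fell (25 and 2 adjusted over the list alone; list adjusted p = 0.000261, 0.56 with an estimated correlation). RUNX2, a factor of bone formation, rose by 1.499 (SE 0.31), from 0.658 to 11.96 CPM, and its call ended without E80 (adjusted p = 0.127). Over the 37 lists tested, 10 passed, 5 up and 5 down, and 0 passed with an estimated correlation, while fry called 16, 9 of them among the 10. With the term for the split at E66 the calls of the Wnt (adjusted p = 0.276), IGF (0.116), S phase (0.157), proteoglycan (0.157), ribosomal protein (0.157) and G2/M lists (0.910, direction up) ended, and those of the lipid (0.00152), collagen (0.000819), lymphatic (0.0258) and mitochondrial lists (0.00221) did not. Of the dissociation stress genes 8 of 22 rose and 1 fell (8 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.0591). It passed upward with the term (adjusted p = 1.80e-07), the lowest p of the lists in that fit.

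The other mesenchymal-like risers named by rule were CLEC3B (1.28), MYLK (1.11), DNAJB1 (1.07), FABP5 (1.05), CAPN6, a calpain (1.04), CPZ, a carboxypeptidase (0.93), NRK, a kinase (0.73), GFRA1, a receptor for glial growth factors (0.86, and adjusted p = 0.0659 without E50) and HSPA1A (1.67). The HSPA1A call (adjusted p = 0.0318) ended without E50 (0.0959), E55 (0.0718), E63 (0.0559) or E80 (0.142), and the DNAJB1 call without E80 (0.0696). The fallers were SNCG (-3.17), CEBPD (-1.33), NSG1 (-1.10), PTGES (-1.04), TNC (-1.03), ZBTB16, a zinc finger repressor (-1.01), GRTP1 (-0.996), UCHL1 (-0.97), MFAP2 (-0.89), HOPX (-0.88) and the chemokine CCL2 (-0.87). The SNCG call ended without E75 (0.0509) or E80 (0.068), the CEBPD call without E80 (0.0717), and the CCL2 call without E55 (0.0731), E60 (0.0564), E69 (0.0502), E75 (0.0586) or E80 (0.117). With the term for the split at E66, 82 genes passed (37 rising, 45 falling), FABP4 (2.50, adjusted p = 0.0212), NUPR1, CLEC3B, MYLK, COL3A1, LUM and HMGA2 among them. Of the 3040 slopes 95.6% kept their direction, which is in part built in, as the genes were called on the same libraries. Within the libraries up to E66, 64 genes passed, within those from E69 16, and up to E69 187, and the rising count of 1418 was 916 without E80.

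In the other classes, HSPA1A and DNAJB1 rose in muscle-like and Schwann-like cells, and NUPR1 rose in tenocyte-like cells. The calls in muscle-like cells ended without E50, E55 or E80. In skeletal-muscle-like cells 1860 of 8241 genes changed, led up by HSPA1A (4.07, SE 0.94, n = 9 libraries), DNAJB1 (2.60, SE 0.61) and BAG3 (2.09, SE 0.43), and down by CRABP1 (-1.93, SE 0.31), CCL2 (-1.52, SE 0.22) and the slow myosin light chain MYL3 (-1.48, SE 0.41). HSPA1A in this class was 6.34 CPM at E69, 990 at E72, 316 at E75 and 1355 at E80. CRABP1 (234 CPM at E50, 4.05 at E80) and CCL2 (60.5 and 4.28) were far below their mesenchymal-like levels (2769 and 414, 391 and 90.1), and how much of these levels is free RNA was not measured. The HSPA1A call ended without E50 (adjusted p = 0.0636), E55 (0.0606) or E80 (0.0594), and that of DNAJB1 without E50 (0.056), E55 (0.0612), E60 (0.0517) or E80 (0.0697). The MYL3 call (0.0395) ended without E55 (0.125), E60 (0.0639), E63 (0.0584), E69 (0.0694), E72 (0.0618), E75 (0.0922) or E80 (0.0851). The count for the class was 1103 without E50 and 1185 without E80, and 22 with the term for the split at E66. In Schwann-like cells, the glia of nerves, 801 of 5393 genes changed, with HSPA1A (3.57, SE 0.59), DNAJB1 (2.25) and CRYAB (2.07) rising, and the pigment cell gene PMEL (-1.60, SE 0.14), UCHL1 (-1.25) and IGFBP2 (-1.26, adjusted p = 0.0138, and 0.126 without E50) falling. PMEL passed with the term for the split (adjusted p = 0.00793), and the class count was 388 without E50 and 2 with the term. In tenocyte-like cells 370 of 4947 genes changed, with NUPR1 (1.53, SE 0.14), COMP, a tendon and cartilage matrix protein (1.02, SE 0.17), and CRYAB (0.98) rising. CENPW, a kinetochore gene (-1.17), UCHL1 (-1.16) and TPX2, a spindle gene (-1.13), fell. CRYAB did not pass without E50 (0.11), E55 (0.0812), E75 (0.0532) or E80 (0.181), nor TPX2 without E50 (0.0739), and the count was 139 without E50, 198 without E80 and 43 with the term.

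**Figure D3:**
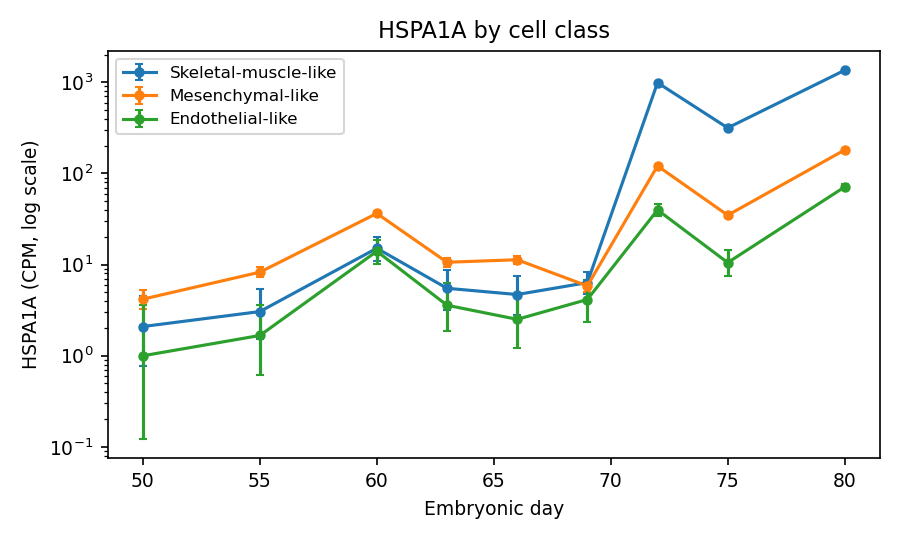
HSPA1A expression (CPM, log scale) against embryonic day in skeletal-muscle-like, mesenchymal-like and endothelial-like cells. Points are libraries, 1 per stage, and bars are 95% exact Poisson intervals of counting error; in muscle-like cells the level is 6.34 CPM at E69 and 990 CPM at E72.

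FABP4 also rose in the cells around vessels. In mural-like cells, the contractile cells around vessels, 403 of 6035 genes changed: FABP4 (2.50, SE 0.29), TRDN, a calcium release protein (1.07, SE 0.16), and RGS2, a brake on G protein signals (0.83), rose, and SH3GL3 (-1.09), EVA1B (-0.95) and CRABP1 (-1.08) fell. TRDN did not pass without E80 (adjusted p = 0.0536), nor CRABP1 without E55 (0.0833), E60 (0.0635), E69 (0.068), E72 (0.0563), E75 (0.0936) or E80 (0.159). The mural-like count was 202 without E50 or E80, 228 without E75 and 1 with the term for the split at E66. In endothelial-like cells 1265 of 8050 genes changed: ARRDC3, an arrestin-like protein (0.79, SE 0.10), COLEC12, a scavenger receptor (0.77, SE 0.18), and OTOR (0.95, adjusted p = 0.0463) rose, and CRABP1 (-1.64), CEBPD (-1.06, adjusted p = 0.0435) and the metallothionein MT1A (-1.02) fell. CRABP1 did not pass without E50 (0.0623), nor MT1A without E80 (0.0542). CRABP1 was 126 CPM at E50 and 4.30 CPM at E80 in endothelial-like and 54.6 and 6.15 CPM in mural-like cells, against 2769 and 414 CPM in mesenchymal-like cells, and how much of these levels is free RNA was not measured. The OTOR call ended without E50 (0.109), E55 (0.0939), E63 (0.0727), E66 (0.0685), E69 (0.0598), E72 (0.0767) or E80 (0.261), and the CEBPD call without E55 (0.0755), E60 (0.0572), E66 (0.0616), E69 (0.0583), E72 (0.0779), E75 (0.106) or E80 (0.142). The endothelial-like count was 791 without E75 or without E80 and 44 with the term.

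Macrophage-like cells, tested in 8 libraries because E50 had 29 of them, had 49 of 4342 genes that changed. IGFBP2 (-1.41, SE 0.21, adjusted p = 0.0043), FBLN1, a matrix protein (-1.09, adjusted p = 0.0261), and IGFBP5 (-2.04) fell, and C4BPA with the identifier ENSOARG00020012814 (1.07), AEBP1 (0.98) and TINAGL1 (0.94) rose; the last 4 each had adjusted p = 0.04998. IGFBP2, IGFBP5, FBLN1 and AEBP1 are abundant in connective tissue cells. Each of the 6 calls ended in at least 1 fit without a library: IGFBP2 without E55 (0.111), and FBLN1 without E75 (0.0794) or E80 (0.0602). IGFBP5 did not pass without E55 (0.285), E63 (0.0521), E69 (0.0973), E72 (0.112), E75 (0.126) or E80 (0.091), and C4BPA without E55 (0.165), E60 (0.144), E63 (0.113), E69 (0.0776) or E75 (0.136). AEBP1 did not pass without E60 (0.0994), E63 (0.109), E66 (0.0653), E69 (0.0532), E72 (0.0528), E75 (0.147) or E80 (0.151), and TINAGL1 without E55 (0.129), E63 (0.104), E66 (0.0618), E72 (0.0544), E75 (0.0702) or E80 (0.47). The count of 49 was 6 without E75 and 9 without E80, and edgeR called 0 with the term for the split at E66, with 174 genes at an unadjusted p under 0.05 and no other tool run with it, while DESeq2 without the term called 73.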

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

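All tests in this part were chosen after the results they address were seen. The libraries of E69 and E72 shared 29 cell barcodes, above the 26 that chance allows from the other pairs, with 8 pairs of copies above the correlation limit of unmatched pairs and 7 E72 copies under 5% of their E69 copies; 14 of the 29 were kept as cells in both libraries. The libraries of E72 and E75 shared 68 cell barcodes, where the other pairs of libraries led to 14.8. Chance alone has an upper limit of 23 for this pair, and the 68 lie above it. In 55 of the 68, the E72 copy held under 5% of the UMIs of its E75 copy, with medians of 666.5 and 37309.5 UMIs over the 68, of which 17 were kept as cells in both libraries; the kept copies of both pairs are part of the shares and sums. A first test set the median correlation of the copies (0.141) against the upper limit of unmatched pairs (0.154) and fell inside it. A count chosen after that found 30 of the 68 pairs above that limit, where 1.7 were expected and chance gave up to 5, so molecules of E75 cells may also have been counted in E72, and no biological explanation was tested.

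The heat shock genes HSPA1A and DNAJB1, which guard protein folding under stress, were higher at E72, E75 and E80 than at E69. From E60 the median log2 changes of 5 heat shock genes to those stages were 0.30, -0.0651 and 0.72 in mesenchymal-like cells. They were -0.20, -0.41 and -0.33 in endothelial-like, 2.92, 3.19 and 3.62 in muscle-like, and 2.63, 2.10 and 3.11 in Schwann-like cells. Stress from dissociation at large could raise immediate-early genes such as FOS with the heat shock genes. The median change of the immediate-early genes from E69 to E72 was -0.31 in mesenchymal-like, 0.29 in muscle-like, 0.14 in endothelial-like and -0.70 in Schwann-like cells. In the same order of classes the medians were 0.40, -0.0584, -0.10 and -0.21 at E75 and 0.28, 0.49, -0.0237 and -0.16 at E80. With each of the 6 libraries up to E69 as the baseline, at least 3 of 4 genes were up every time in muscle-like cells at E80 alone, and in no class and library were at least 3 of 4 down every time; in mesenchymal-like cells at E72 between 2 and 5 genes were up. Stress of that kind fits muscle-like cells at E80 and stays open elsewhere. Muscle genes reached a median of 1.57, 1.12 and 0.714% of their muscle level in mesenchymal-like cells at E72, E75 and E80, and HSPA1A 12.2, 11.0 and 13.3%. By that median RNA of muscle cells was not enough. Single muscle genes reached up to 50.6, 20.4 and 21.0%, so HSPA1A lies within their spread. With at most 1 library per stage, the handling of a library and the stage cannot be told apart.

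FABP4 and LPL rose in the mesenchymal-like sums, where free RNA of adipocyte-like cells, or such cells placed in the class, are technical explanations. At E80 the ratio of FABP4 to LPL was 3.06 (interval 2.84 to 3.30) in mesenchymal-like and 8.18 (7.90 to 8.46) in adipocyte-like cells. LPL was 27.8 CPM in mesenchymal-like and 1.80 CPM in muscle-like cells, so free RNA does not account for the whole LPL level. LPL had 781 UMIs in the whole tissue up to E66, where the adipocyte-like cluster held no cells. A low ratio can thus come from LPL of other cells, and it leaves the source of FABP4 open. The ratios also lay apart at E69, E72 and E75 (1.16, 1.61 and 3.77 against 11.1, 8.88 and 6.34). ADIPOQ was 0.508 CPM at E80 (upper limit 0.814), where misplaced adipocyte-like cells that carried the FABP4 would bring 2.05 CPM. That level assumes the ADIPOQ to FABP4 ratio of the adipocyte-like cluster and has no interval, so misplaced cells with less ADIPOQ per FABP4 are not covered. The upper limits of ADIPOQ were also below that level at E69 (0.110 against 0.228), E75 (0.875 against 1.86) and, narrowly, E72 (0.709 against 0.728). A biological change with stage in mesenchymal-like cells therefore may remain, as a hypothesis found and tested on the same data. How much of the FABP4 and of the LPL is free RNA stays open.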

How the results depend on the processing

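The term for the split at E66, the fits within or up to a stage, haemoglobin in the top 10, low-depth clusters named and centred shares were chosen after seeing the data; where a value below moved or turned, the cause was not tested. No paired analysis was possible because each stage had 1 library. Shares of non-erythroid-like cells were not run because no class was erythroid-like, and the fit without haemoglobin genes removed those genes only. Of 2994 values of 181 named-gene results under the alternatives, 2601 kept direction and side of the threshold (86.9%), 380 were weaker, 4 stronger and 9 reversed. With a library left out 1419 were the same, 193 weaker, 4 stronger and 3 reversed. Genes named by rule had to pass and to keep their sign in those fits, so their agreement there is in part fixed by the choice. In the other settings 1182 were the same, 187 weaker and 6 reversed. For gene lists, 119 values of other settings were the same, 36 weaker, 13 stronger and 8 reversed, and with a library left out 364, 12, 14 and 6. For counts and class shares, 130 values of other settings were the same, 45 moved, 5 were stronger and 5 reversed, and with a library left out 192, 26, 3 and 3. With equal cells and UMIs per library, 2464 whole-tissue genes passed; depth was not equalised for the smaller classes.

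With the term for the split at E66, counts were 66 (30 rising, 36 falling) in the whole tissue, 82 (37, 45) in mesenchymal-like, 44 in endothelial-like, 0 in macrophage-like (edgeR, 174 at an unadjusted p under 0.05), 1 in mural-like, 2 in Schwann-like, 22 in muscle-like and 43 in tenocyte-like cells, and 6 mesenchymal-like lists passed. Slopes that turned with it in the whole tissue were TCF21 at -0.0404, PAX7 at -0.22 and MYH3 at -0.79. Of the lists named in the text, those that turned were, in the whole tissue, brown fat (adjusted p = 0.452), cytosolic ribosomal protein (0.764), glycolysis and hypoxia (0.201), lymphatic endothelial (0.703) and cartilage matrix genes (0.441), and in mesenchymal-like cells G2/M phase (0.910), glycolysis and hypoxia (0.276) and cartilage matrix genes (0.918). Lists not otherwise named that turned without passing either way were, in the whole tissue, muscle progenitor (0.261), BMP and TGF-beta (0.438), epidermal barrier (0.888), Schwann cell (0.426) and MHC and interferon genes (0.0900), and in mesenchymal-like cells BMP and TGF-beta (0.8004), tendon (0.455), hair follicle (0.910) and erythroid genes (0.608). Calls ended without a turn for Wnt (0.173), IGF (0.221) and G2/M genes (0.321) in the whole tissue and for Wnt (0.276), IGF (0.116), S phase, proteoglycan and ribosomal protein genes (0.157 each) in mesenchymal-like cells. Calls began with it for muscle contractile (1.45e-06, down), fibrillar collagen (0.00638, up), posterior HOX (0.00974, down), basement membrane (0.0132, up) and erythroid genes (0.0139, up) in the whole tissue and for dissociation stress (1.80e-07, up) and imprinted growth genes (0.0349, up) in mesenchymal-like cells. Up to E66 only, counts were 30 (15 and 15) and 64 (37 and 27) in the whole tissue and in mesenchymal-like cells; from E69 only, 0 (0 and 0; edgeR, 1661 at an unadjusted p under 0.05) and 16 (13 and 3); up to E69, 108 (44 and 64) and 187 (93 and 94).

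Scaling by library size alone gave 828 rising and 2346 falling whole-tissue genes and 612 rising and 2716 falling mesenchymal-like genes, as it moved the median slope of all genes to -0.04 and -0.07. MYOD1, not called, was 0.0771 with equal cells and UMIs, and with marker-score classes CEBPA was -0.49 and PAPPA2 -0.69 in mesenchymal-like cells. Of the gene lists, 0 passed in either tissue sum with an estimated correlation, and fry called 20 and 16. Class shares past Pearson's r were 4 with marker-score classes and 2 with strict cells; by rank they were 2 at resolutions 0.5 and 2.0, 1 with doublets kept or haemoglobin in the top 10, and 0 with shares centred on each side of E66, where r turned for Schwann-like (0.00481) and muscle-like shares (-0.348). The rank calls that ended were the muscle-like share at resolutions 0.5 (adjusted p = 0.0865) and 2.0 (0.0642), with marker scores (0.461), doublets kept (0.0779), strict cells (0.605) and haemoglobin in the top 10 (0.0642); the tenocyte-like share at both resolutions (0.310 and 0.319), with doublets kept (0.0765) and haemoglobin in the top 10 (0.0642); and the mesenchymal-like share with marker scores (0.461), doublets kept (0.0765) and haemoglobin in the top 10 (0.375). With marker-score classes r was 0.870 for adipocyte-like, 0.227 for keratinocyte-like, -0.816 for mural-like, -0.828 for Schwann-like and -0.995 for tenocyte-like shares. With strict cells it was 0.805 for adipocyte-like and -0.834 for tenocyte-like shares, and with low-depth clusters named -0.0155 for endothelial-like shares.

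With 1 library left out, whole-tissue counts ran from 2109 (E50) to 2997, rising from 876 (E80) to 1336, falling from 1142 (E50) to 1692, and mesenchymal-like rising from 916 (E80) to 1313. Counts ran from 791 (E75 or E80) to 1248 in endothelial-like, 6 (E75) to 50 in macrophage-like, 202 (E50 or E80) to 403 in mural-like, 388 (E50) to 776 in Schwann-like, 1103 (E50) to 1798 in muscle-like and 139 (E50) to 358 in tenocyte-like cells. Classes past Pearson's r ran from 0 to 2 and by rank from 0 to 4. Share correlations ran from 0.695 to 0.850 (adipocyte-like), -0.0384 (E80) to 0.504 (endothelial-like), -0.764 (E55) to -0.179 (E50, keratinocyte-like), -0.173 (E50) to 0.294 (macrophage-like), -0.241 (E80) to 0.280 (mural-like) and -0.907 to -0.555 (tenocyte-like). MYOD1 ran from -0.20 to 0.18. Lists that did not pass and turned in some fit had adjusted p from 0.579 to 0.988 (lymphatic endothelial), 0.252 to 0.971 (fibrillar collagen), 0.182 to 0.514 (muscle contractile) and, in mesenchymal-like cells, 0.590 to 0.822 (macrophage genes).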

Other observations

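The test of glucocorticoid-responsive genes was set before its result was seen; the comparison of neighbouring stages and the permuted orders of the days were chosen after the results they address were seen. Expression differed more between E66 and E69 than between other neighbouring stages, by a mean of 0.21 log2 units in the whole tissue (0.17 for the next, E50 to E55) and 0.20 in mesenchymal-like cells (0.19 for the next). With equal cells and UMIs these were 0.20 and 0.17 in the whole tissue. CEBPD was lower at E69 than at E66 in each of the 7 classes tested, with the E66 level 2.30 (muscle-like) to 4.25 times (mural-like) that of E69. The E66 level of MT1A, a metallothionein, was 1.23 (muscle-like) to 5.18 times (tenocyte-like) that of E69 in 6 of these classes, and macrophage-like cells had 11 UMIs of it at E66 and 1 at E69. CCL2, a chemokine that draws monocytes, was 3.46 times higher at E66 in the whole tissue, while in endothelial-like cells it was 61.4 CPM at E66 and 234 CPM at E69.

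Clusters inside the classes held further cell types. A cluster with CCL21, LYVE1 and PROX1, markers of lymphatic vessels, made up 36.1% of the 61 endothelial-like cells at E50 (interval 24.2 to 49.4), 18.9% at E55, 20.2% at E60, 7.74% at E63, 19.1% at E66, 13.4% at E69, 12.4% at E72, 3.68% at E75 and 9.72% at E80 (7.10 to 12.9). These shares leave out an unnamed cluster of low depth led by APOA1, PLVAP and PECAM1. That cluster held 44 cells at E50, 92 at E63 and 34 at E80, so the high share at E50 depends on the depth rule. A cluster of muscle-like cells was led by MYL11, MYH3 and MYH8, genes of embryonic and newborn muscle fibres. In the whole tissue 1 of 10 lymphatic endothelial genes rose and 1 fell (1 and 1 adjusted over the list alone; median slope 0.10, camera direction down, adjusted p = 0.967). Of the small leucine-rich proteoglycan genes 5 of 11 rose and 2 fell there (5 and 2 adjusted over the list alone; adjusted p = 0.188), and of the fibrillar collagen genes 5 of 19 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.702), and that list passed upward with a term for the split at E66 (adjusted p = 0.00638).

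The unnamed clusters held 7.10% of the kept cells at E50, 3.69% at E55, 5.50% at E60, 6.11% at E63, 4.90% at E66, 2.68% at E69, 2.44% at E72, 2.71% at E75 and 2.95% at E80. Most were cells of low depth, 6.43% of the kept cells at E50 and 1.97% at E80. With haemoglobin in the top 10 as the bar, the mesenchymal-like share had r = -0.393 in place of -0.664.

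The fall of CEBPD, ZBTB16 and MT1A, which glucocorticoid hormones induce, could reflect lower expression of glucocorticoid-responsive genes at large from E69. The median difference of the other listed genes lay at percentile 4.76 of 10000 matched random lists, with 4 of the 10 genes measured above a floor of 5 CPM. The floor was not fixed beforehand, and at floors of 1, 2 and 10 CPM the percentiles were 24.6, 0.86 and 0.81 with 8, 5 and 3 genes, so the test leaves the hypothesis undecided.

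None of the permuted orders drawn gave as many genes as the real order of the days, and 1 of 100 is the lowest share that 100 orders can give. Of 100 orders of the days, only the real one, 1 of 100, gave as many as 3197 whole-tissue genes, with 1894 in the highest other order, and 1 of 100 gave as many as the 3040 mesenchymal-like genes, with 2004 in the highest other. The whole-tissue orders with the next counts gave 1746 and 3. Both orders with over 1000 genes correlated with the split between E66 and E69 at 0.832 and -0.843, where the real order has 0.832. They also correlated with the real day, at 0.821 and -0.722. The counts thus point to a structure of the samples along the split or the day, which the permuted orders cannot tell apart. With a term for the split 66 and 82 genes passed.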
